A study of Saccharomyces cerevisiae with 50 samples.

How the data were processed

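The series holds 50 dual-colour arrays in 18 groups of 2 or 3, each array hybridised with immunoprecipitated or mononucleosomal DNA in one dye and input or genomic DNA in the other. The assays are ChIP of Rsc3, Rsc8, histone H4 and Rpc82, and mononucleosomal DNA of Sth1 degron, control and rpb1-1 strains. Crosslinking lasted 30 min for Rsc3, Rsc8 and Rpc82, 15 min for H4 and 5 min for mononucleosomes. Copper was at 0.05 mM in the degron and control cultures, and rpb1-1 cells grew at 23 C before 120 min at 37 C. Groups, strains, times and dyes were taken from the labels. The immunoprecipitated or mononucleosomal DNA is in Cy5 on all arrays except those of the Rpc82 control strain, where the labels put it in Cy3. The values bear this out, since the red over green ratios of those 6 arrays correlated with the degron arrays at r between -0.975 and -0.832. The source name of the Rpc82 control group before induction reads "after", while its title, description and protocol say before, and the last 3 were followed. The description of the second degron array after induction carries the number 1, and its title was followed.

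Spot intensities of both channels were subtracted by the authors' scanner software, Feature Extraction 8.5.1.1, for the mean local background and dye-normalized by lowess on a chosen list of probes, with no spatial detrending, per the file headers. The list held 281 probes for the Rsc3 and Rsc8 arrays and 312 for all others, with 138 in common. The log10 ratios that the same software deposited are red over green of those signals, per the file headers, and 97 dim spots carry a ratio of 0 there. The log2 values in the series table are the authors' log10 ratios converted to base 2, with the sign turned for the 6 Rpc82 control arrays. They were not centred, as deposited, with array medians between -0.31 and 0.37, and 1733 of them are blank. How the blanks were chosen is not stated.

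Each array carries 1900 spots, of which 4 are negative controls and 1896 are probes of 60 nucleotides. The probes tile 211 loci with a median of 8 probes each (4 to 21) at a median spacing of 107 bp. The log2 ratio of immunoprecipitated over input signal, or of mononucleosomal over genomic DNA, was computed from the processed intensities. Spots that the software called non-uniform (15 to 915 per array, 17831 in all) were left out, and each array was centred on its median. Saturated spots (0 to 82 per array, 471 in all) were kept, and a change at a probe saturated or not well above background on every array of a group is given only as a bound or without a fold. Between 99.6% and 100% of probes were well above background. The probe names give chromosome positions without a build, and the build is not given in the sources used here. Names of genes and neighbours came from assembly R64. Start codons and box B sequences in the probes were compared with R64, and the shift that matched best was -84 bp on chromosome X (5 start codons and 1 box B). On chromosomes II, III, IV, V and XI the best shifts lay 45 bp or more from 0 but rested on at most 3 matches, most of them tied. Because the build stays uncertain the probe, not the gene or promoter, is the unit of every test, which is the fallback written into the design. Loci are groups of probes less than 500 bp apart. A probe counts as Pol III if its midpoint lies within 50 bp of a Pol III gene, or on chromosomes X and XI if it holds a box B of a tRNA gene. This gives 88 probes in 50 loci, while 54 loci hold such a gene. Probes of the remaining Pol III loci are not in the list and count among other loci. All other probes count as gene body (470), intergenic (881) or boundary (457). For the other lists a probe counts if its midpoint lies in a listed gene or at most 300 bp upstream. On chromosomes X and XI every probe of a locus that overlaps the gene counts. This takes all probes of the SNR69 and SNR42 loci into the snoRNA list, neighbouring sequence included.

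Tests used limma 3.58.1 in R 4.3.3, with tables and figures made in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9). A cell-means model was fitted to each family of arrays, 12 for Rsc3 and Rsc8, 8 for H4, 12 for Rpc82, 12 for degron and control mononucleosomes and 6 for rpb1-1, with default empirical Bayes moderation. A call is a Benjamini-Hochberg adjusted p under 0.05 over the probes of a comparison, and enrichment before induction also needed at least 1 log2. SE is the moderated standard error and SD the spread between arrays. Lists of at least 5 measured probes were tested with limma's camera on the moderated statistics at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The probes of a list lie side by side in a few loci, so the preset value is low for them. The list of ribosomal protein genes also holds RPP1, which codes for an RNase P subunit and not a ribosomal protein. Its probes enter every count, median and test of that list. Array means were compared by exact permutation. For differences between the strains, same-numbered arrays were taken as pairs, in the SE too. Pol III genes in the degron and control strains were compared at one time point by no test for Rpc82, because dye and strain coincide there.

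Probes named in the text follow a rule of the design: the 10 largest rises and falls among calls with one sign in every pair of arrays of the same number, 1 per gene, and 2 to 4 members of each list. For enrichment the 15 highest were eligible, and for mononucleosomes also the 10 longest runs of at least 3 neighbouring calls and the loci of at least 6 probes with the largest share called. The text prints a selection of these, and where fewer than 10 passed, the 5 largest others were eligible as values. HHF2 is the only gene of the genotypes on the array.

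In all 25 physical arrays on 5 slides were each used 2 times, with scans 1 to 4 days apart, first for a sample after induction and then for the one before with the same number (for rpb1-1 first permissive, then non-permissive). Rsc3 and Rsc8 share a slide, as do Rpc82 and degron H4, and mononucleosomes and control H4. The protocol takes the sample before induction from the culture that is then induced, but the labels do not say that equal numbers mean one culture. Deviations of same-numbered arrays from their group means were therefore correlated. Among strains with 3 pairs, every pair passed 0.1 only for the Rpc82 control strain (r 0.20 to 0.48). The ranges were 0.03 to 0.30 for Rsc3, -0.24 to 0.21 for Rsc8, 0.03 to 0.28 for Rpc82 degron, -0.23 to 0.11 and -0.07 to 0.07 for degron and control mononucleosomes, and -0.07 to 0.02 for rpb1-1. The H4 pairs, 2 per strain, gave 0.18 in the degron strain and -0.01 in the control strain.

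The fits were tested on simulated arrays (seed 11) with 200 changed probes. At 1 log2, 66 of 67 changes were recovered for Rsc3, 53 of 56 for degron H4, 38 of 63 for degron Rpc82, 50 of 53 for degron mononucleosomes and 57 of 63 for rpb1-1. At 0.5 log2 the strain differences recovered 24 of 51 for H4, 5 of 62 for Rpc82 and 26 of 59 for mononucleosomes. Unchanged probes gave 0 to 11 calls. The simulated noise was independent between probes, so it cannot give the false positive rate for lists of neighbouring probes. Of 200 simulated lists of 40 scattered unchanged probes 0 to 1% had p under 0.05 for changes. For enrichment, where every simulated probe moved up and the list test compares with the other probes, 20% did for Rsc3 and 30.5% for Rsc8. Alternatives were normexp background correction (offset 50), loess within arrays, centring on the mode, one spread for all arrays, only probes well above background, the authors' values, the replicate number as a block, a variance trend, no size minimum, the sign of the Rpc82 control arrays turned, and each array left out in turn. The normexp values start from the raw mean signals and median local backgrounds, so they also lack the dye normalization of the scanner software. The authors' values were centred on the median of each array before they were tested. Keeping non-uniform spots, leaving out saturated ones and using 1 rpb1-1 slide alone were added after the data had been seen.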

Results

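RSC is an essential ATP-dependent chromatin remodelling complex of budding yeast, with Sth1 as its catalytic subunit, Rsc3 as a zinc-cluster DNA-binding subunit and Rsc8 as a core subunit. The series measured chromatin on 50 dual-colour tiling arrays with 1896 probes in 211 loci picked by the study among RSC targets. Of these loci 54 hold a gene transcribed by RNA polymerase III (Pol III). Immunoprecipitated (ChIP) or mononucleosomal DNA was hybridised against input or genomic DNA. Every value is a log2 ratio relative to the median of its array. ChIP of Rsc3 and of Rsc8 used strains with intact Sth1, sampled before and after a mock induction, with 3 arrays in each of 4 groups. ChIP of myc-tagged histone H4 (2 arrays per group), ChIP of the Pol III subunit Rpc82 (3 arrays per group) and mononucleosome maps (3 arrays per group) compared a degron strain with a control strain, each before and after induction. In the degron strain Sth1 carries a tag that marks it for degradation once galactose induces Ubr1 and the culture is warmed. The control strain carries the tagged Sth1 but lacks UBR1. Cultures grew at 27 C in raffinose, received galactose for 60 min and then stood at 37 C for 120 min. Mononucleosomes of an rpb1-1 strain, whose RNA polymerase II (Pol II) is heat-sensitive, were mapped at a permissive and a non-permissive temperature with 3 arrays each.

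The number of arrays limits the precision. Median signal over background lay between 35.5 and 241 in the green channel and between 14.9 and 109 in the red channel. Arrays of one group correlated across probes with r between 0.693 and 0.985. The labels call the arrays of a group biological replicates, and the p-values measure the spread between them. Positions are those of the array design, whose genome build is not stated. Gene names come from the neighbouring genes in the R64 annotation, and names that begin with YNC are tRNA genes there. The same physical array was hybridised first with an after sample and then with the before sample of the same number (for rpb1-1 first permissive, then non-permissive), so array use and induction cannot be told apart in any comparison of after with before.

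The first question was where RSC lies on these loci before any induction. Upstream of TIM23, a subunit of the mitochondrial import channel, the Rsc3 ratio was 1.13 ± 0.01 log2 (SD, n = 3; chromosome XIV, 662704). Upstream of HEM1, which starts haem synthesis, it was 0.91 ± 0.11, and upstream of MSS4, a phosphatidylinositol phosphate kinase, 0.85 ± 0.08. Upstream of ZWF1, glucose-6-phosphate dehydrogenase, it was 0.82 ± 0.07, and upstream of PMI40, phosphomannose isomerase, 0.78 ± 0.07. All 38 probes at histone genes lay above the array median with adjusted p under the threshold, with a median of 0.37. Among them were the promoters of HTA1 (0.60 ± 0.10) and of HTZ1 (0.55 ± 0.07). Pol III gene probes lay slightly below the array median, at -0.08, although the probe beside the 5S rRNA gene RDN5-1, saturated on 2 of 3 arrays, reached 0.76.

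A call required an adjusted p under 0.05 and at least 1 log2 above the array median. For Rsc3, 8 of 1890 probes at 4 loci met it: TIM23/RCF2, OM14/COQ21 (1.07 ± 0.06 inside COQ21, chromosome II, 680386), ALY2/TAX4 (1.07 ± 0.13, chromosome X, 278523) and the right end of chromosome I near PHO11 (1.13 ± 0.02, position 230007). With no size minimum, 1467 probes differed from the array median with adjusted p under the threshold, 737 of them above it. Rsc8 ranked the same promoters high, with TIM23 at 1.00 ± 0.04 (position 662804), OM14 at 0.79 ± 0.05, HEM1 at 0.68 ± 0.02 and PMI40 at 0.63 ± 0.04. DPM1, dolichol phosphate mannose synthase, was at 0.60 ± 0.06 and the Mediator gene SRB2 at 0.59 ± 0.04. No probe passed the 1 log2 minimum for Rsc8 in limma, against 1391 probes at an unadjusted p under 0.05. With no size minimum 695 were called higher, and with the minimum 5 were called with normexp background correction and 2 with arrays centred on the mode. Across 1890 probes the Rsc3 and Rsc8 levels correlated with r = 0.94, and probes are not independent replicates. The Rsc3 count was 22 with normexp, 1 after loess, 0 with arrays scaled to one spread and 5 without Rsc3 before replicate 1. In the authors' values, centred on the median of each array, it was 5. As deposited, the medians of these arrays lay between 0.33 and 0.37, and no count was made without centring. The 1 log2 minimum sits close to the upper end of the measured ratios.

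**Figure D1:**
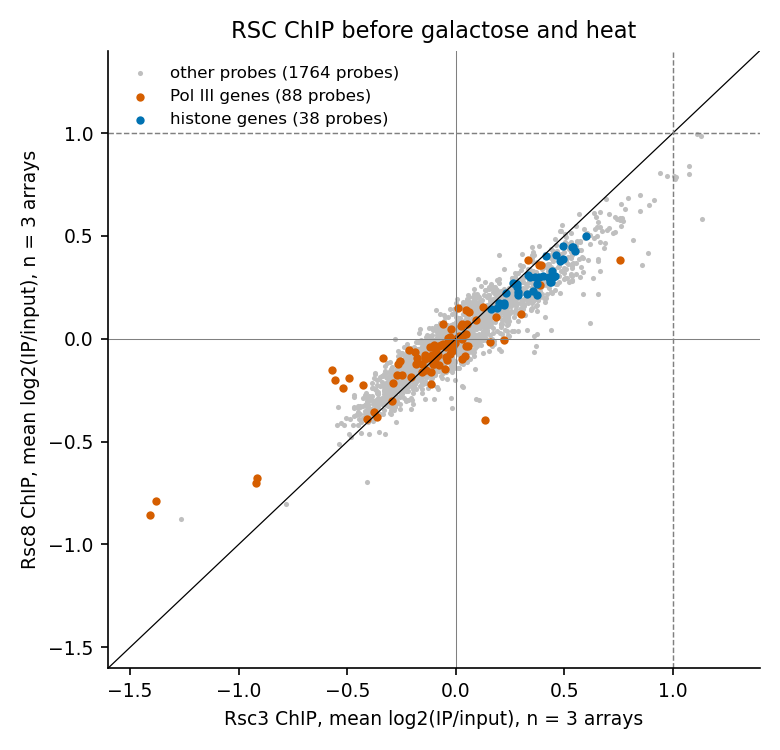
Mean log2(IP/input) of each probe before induction for Rsc3 (horizontal axis) and Rsc8 (vertical axis), 3 arrays each, with Pol III gene probes in orange, histone gene probes in blue and all others in grey; the solid diagonal marks equal values and the dashed lines 1 log2. The 38 histone gene probes all lie above 0 on both axes, and 8 probes pass 1 log2 for Rsc3 and none for Rsc8.

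Of the gene lists fixed before the data were examined, histone genes stood above the other probes for Rsc3 (adjusted p = 5.9e-12) and Rsc8 (median 0.29, adjusted p = 6.9e-12). This was lost with an estimated correlation (adjusted p = 0.18 in each). The cell wall list is a single locus here, YPS1, a cell surface protease (medians 0.43 and 0.36, adjusted p = 0.022 and 0.030). The phosphate list is PHO8, a vacuolar phosphatase (0.42 and 0.28, adjusted p = 0.014 and 0.015). Neither held with an estimated correlation (adjusted p = 0.61 for both in Rsc3, and 0.67 and 0.63 in Rsc8), and YPS1 was lost with one spread (adjusted p = 0.054 and 0.067). Pol III genes lay below other probes in the Rsc3 and Rsc8 ChIP (adjusted p = 0.022 and 0.030; adjusted p = 0.73 and 0.77 with an estimated correlation). Their medians turned to 0.03 and 0.05 after loess (adjusted p = 0.63 and 0.57), and the calls were lost with one spread (adjusted p = 0.054 and 0.051) and over probes well above background (adjusted p = 0.052 and 0.059). Ribosomal protein genes (-0.03 and -0.03), galactose genes (-0.14 and -0.11; passing with normexp at -0.25 and -0.14, adjusted p = 0.010 and 0.031), nitrogen genes (0.01 and 0.06, where the second turns to -0.05 after loess) and snoRNA genes (-0.02 and 0.03) did not pass. No member of any list reached a call, over all probes or adjusted over the list alone. The lists of heat shock genes (GSY2, -0.05 for Rsc3) and carbohydrate genes (CIT1, -0.18) were too small to test. HHF2, the one gene of the strains' genotype on the array, had a median of 0.43 for Rsc3.

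The second question was what the mock induction, galactose and heat with Sth1 intact, does to RSC itself. Rsc3 fell at several promoters where it had been high and rose over Pol III genes. It fell by 0.55 log2 near STP4 (SE 0.04, adjusted p = 2.9e-06; from 0.33 ± 0.07 to -0.23 ± 0.02, n = 3), by 0.47 between DIC1, a mitochondrial carrier, and ORM2 (SE 0.05) and by 0.45 at SRB2 (SE 0.06). It also fell by 0.44 at ILV3 of branched-chain amino acid synthesis (SE 0.06) and by 0.43 at COX20/HEM1 (SE 0.06). It rose by 0.76 beside the tRNA gene YNCJ0006W (SE 0.17, adjusted p = 0.0023) and by 0.58 in YNCP0018C. Further rises were 0.55 near TFC3, a subunit of the Pol III factor TFIIIC (SE 0.10), and 0.54 beside YNCI0003C. At the galactose genes, GAL10 rose by 0.45 (adjusted p = 3.4e-05) and GCY1 fell by 0.25. Of 1890 probes 1069 changed, 509 higher and 560 lower. Across the 1890 probes the Rsc3 change correlated with the Rsc3 level before induction at r = -0.73 (-0.69 for Rsc8). The before arrays enter both values. The SD of the ratios on an array was 0.27 to 0.31 before and 0.18 to 0.24 after. For Rsc8 it was 0.22 to 0.24 and then 0.18. Narrowing of all ratios towards the array median also lowers high places and raises low ones. Counts with arrays scaled to one spread are given below.

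Rsc8 moved in the same directions. It rose by 0.40 in the tRNA gene TRR4 (SE 0.11, adjusted p = 0.015), by 0.30 at GAL10 (SE 0.05), by 0.28 near RPS3 of the ribosome and by 0.27 upstream of RPR1, the RNase P RNA gene (SE 0.04). It fell by 0.50 beside PUT1, the proline oxidase gene (SE 0.09), by 0.42 upstream of HTA1 (SE 0.06), by 0.40 at SRB2 and at MSS4 (SE 0.06 each) and by 0.36 near TIM23 (SE 0.06). The largest fall, beside RDN5-1 (SE 0.23), holds 1 saturated array. The probe near PHO11 that passed was saturated on all 3 after arrays, so no fold is given there. In all 709 probes changed for Rsc8, 285 higher and 424 lower. Of these 584 were called for Rsc3 and Rsc8 alike, 226 higher and 353 lower in both and 5 opposite, where independent lists would share 76.8 and 126. Centring on the mode gave 683 and 304 calls (68 higher and 236 lower for Rsc8). Scaling to one spread gave 661 for Rsc3, and leaving out Rsc8 after replicate 1 gave 432 for Rsc8. The Rsc3 probes at YIL001W, YNCB0018W and YNCM0010W that passed were not well above background on any before array and have no usable bound.

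Pol III genes rose in the Rsc3 ChIP, 49 of 88 probes higher and 4 lower (53 adjusted over the list alone; median 0.13, adjusted p = 2.8e-07; adjusted p = 0.26 with an estimated correlation). They rose in the Rsc8 ChIP too, 29 higher and 5 lower (34 adjusted over the list alone; 0.10, adjusted p = 2.1e-06; adjusted p = 0.20 with an estimated correlation). After loess the medians were 0.03 and 0.02 and neither passed (adjusted p = 0.19 and 0.076; 24 higher and 6 lower for Rsc3, 18 and 7 for Rsc8). Centred on the mode 33 and 0 Pol III probes were called for Rsc3, and 6 and 3 for Rsc8. Histone genes fell, 27 of 38 probes for Rsc3 (29 adjusted over the list alone; -0.13, adjusted p = 1.2e-06) and 25 for Rsc8 (29 adjusted over the list alone; -0.14, adjusted p = 1.7e-07). With an estimated correlation these gave adjusted p = 0.26 and 0.20, and with arrays scaled to one spread the medians were -0.02 and -0.05 (adjusted p = 0.43 and 0.12). All 5 probes of YPS1 fell (-0.34 and -0.40, adjusted p = 0.0083 and 0.00041), as did all 5 of PHO8 (-0.33 and -0.24, adjusted p = 0.0031 and 0.0016; 5 adjusted over the list alone in each). None of these held with an estimated correlation (adjusted p = 0.26 for Rsc3 and 0.20 for Rsc8), and YPS1 for Rsc3 was lost with one spread (-0.20, adjusted p = 0.067). The ribosomal protein list rose, 9 and 6 of 24 probes (8 and 4 adjusted over the list alone; 0.10 and 0.09, adjusted p = 0.0059 and 0.0014; adjusted p = 0.26 and 0.20 with an estimated correlation). This list also holds RPP1, an RNase P subunit gene, wherever it is used here. Galactose genes (7 higher and 4 lower of 12 for Rsc3, 3 and 1 for Rsc8), nitrogen genes (5 lower of 14, and 1 higher and 8 lower) and snoRNA genes (5 and 11 of 37, and 5 and 3) did not pass as lists. Adjusted over the list alone they gave 11, 9, 5, 10, 16 and 5 calls. Nitrogen genes passed in the authors' values (-0.11 in each, adjusted p = 0.040 and 0.039), with normexp (-0.13 and -0.15, adjusted p = 0.021 and 0.032) and with one spread (-0.10 and -0.11, adjusted p = 0.0495 and 0.015), and for Rsc8 centred on the mode (-0.13, adjusted p = 0.016).

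Rsc8 was set directly against Rsc3 before induction. Rsc8 gave lower ratios than Rsc3 at several of the most enriched places, by 0.55 near PHO11 (1.13 ± 0.02 against 0.58 ± 0.14, n = 3), by 0.41 at STP4 and by 0.34 at ZWF1. It was lower by 0.28 at CAR2, the ornithine aminotransferase gene, and by 0.27 in PMI40. It gave higher ratios by 0.36 beside YNCI0003C, by 0.28 upstream of the proteasome gene SEM1 and by 0.21 upstream of SRP72, a signal recognition particle gene. In limma 172 probes differed, 59 higher and 113 lower for Rsc8. Histone genes had 4 of 38 probes lower (11 adjusted over the list alone; median -0.08, adjusted p = 1.6e-05; adjusted p = 0.80 with an estimated correlation; -0.01 with one spread, adjusted p = 0.96), and HHF2 had 3 of 5 lower. No other list passed, with medians between -0.10 for PHO8 and 0.02 for Pol III genes. The count fell to 16 with arrays centred on the mode (3 higher and 13 lower), 0 with arrays scaled to one spread and 18 without Rsc8 before replicate 2. It was 264 without Rsc3 after replicate 2, and normexp split it 109 higher and 127 lower.

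H4 ChIP addressed nucleosome density before and after loss of Sth1. In the degron strain H4 rose by 1.15 log2 over SNR17A, the U3 snoRNA gene (SE 0.09, adjusted p = 8.3e-07; from -2.18 ± 0.13 to -1.03 ± 0.10, n = 2) and by 1.01 between COA6 and FAA4 (SE 0.09). It rose by 0.87 near TIM23/RCF2 (SE 0.13) and by 0.65 upstream of ALD6, an aldehyde dehydrogenase gene (SE 0.08). It fell by 1.49 near HOR7 (SE 0.11, adjusted p = 8.3e-07), by 1.12 upstream of ZWF1 (SE 0.11), and by 1.11 at YCR022C (SE 0.10). The change was -1.10 near TOS3, a kinase gene (SE 0.10), and -0.82 in SCR1, the signal recognition particle RNA gene (SE 0.11; 0.26 with normexp). Galactose genes fell, 4 of 7 probes lower (4 adjusted over the list alone; median -0.63, adjusted p = 0.0045; adjusted p = 0.12 with an estimated correlation; -0.50, adjusted p = 0.087 with one spread). GCY1 was at -0.91 and GAL10 at -0.70. In all 454 of 1514 probes changed, 209 higher and 245 lower.

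Pol III genes fell in the degron strain, 28 of 77 probes lower and 1 higher (32 adjusted over the list alone; median -0.21, adjusted p = 2.5e-06; adjusted p = 0.46 with an estimated correlation). Centred on the mode 4 of these probes were lower and none higher, and with normexp 11 were lower and 11 higher. The snoRNA list rose, 10 of 28 higher and 2 lower (12 adjusted over the list alone; 0.17, adjusted p = 0.00075; adjusted p = 0.076 with an estimated correlation). In every comparison this list takes in neighbouring sequence, with all probes of the SNR69 and SNR42 loci. Ribosomal protein genes had 5 higher and 3 lower of 19 probes (8 adjusted over the list alone; median 0.04), and histone genes 5 and 6 of 36 (13; 0.04). Nitrogen genes had 1 lower of 7 and YPS1 none of 5 (-0.08, turning to 0.01 with one spread). None of these lists passed, though nitrogen genes did in the authors' values (-0.17, adjusted p = 0.027) and with outlier spots kept (-0.18, adjusted p = 0.024). The count was 281 with the replicate number as a block, 114 with arrays centred on the mode and 236 without degron after replicate 1. The Pol III median was -0.09 with normexp (adjusted p = 0.89), -0.35 without degron after replicate 2 and -0.12 without degron after replicate 1.

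In the control strain H4 fell over Pol III genes, with 70 of 77 probes lower and 1 higher (1 higher and 71 lower adjusted over the list alone; median -0.97, adjusted p = 4.0e-35). This held with an estimated correlation (adjusted p = 0.018). SCR1 fell by 1.73 (SE 0.15, 1 after array) and the RNase P RNA gene RPR1 by 1.68 (SE 0.14; from 0.13 ± 0.27 to -1.55 ± 0.30, n = 2). The tRNA genes fell too, SUF11 by 1.71 (1 after array), YNCO0008W by 1.68 (SE 0.10) and YNCL0047W by 1.58 (SE 0.11). Galactose genes fell, 6 of 7 probes (6 adjusted over the list alone; -0.77, adjusted p = 2.8e-05; adjusted p = 0.017 with an estimated correlation). Among them GAL1 was at -0.95. H4 rose upstream of SNR17A by 1.09 (SE 0.08, adjusted p = 1.0e-07), near TIM23/RCF2 by 1.03 and upstream of SES1, seryl-tRNA synthetase, by 1.04 (-0.03 with normexp). The snoRNA genes rose as a list (11 of 28 higher, 11 adjusted over the list alone; 0.21, adjusted p = 0.0025; adjusted p = 0.043 with an estimated correlation). So did ribosomal protein genes (11 higher and 1 lower of 19, 12 adjusted over the list alone; 0.31, adjusted p = 0.014; adjusted p = 0.038 with an estimated correlation).

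Histone genes had 13 higher and 2 lower of 36 probes in the control strain (15 adjusted over the list alone; median 0.14, which turns to -0.01 with normexp and -0.04 centred on the mode). YPS1 had 2 lower of 5 and nitrogen genes 1 lower of 7 (0 adjusted over the list alone). None of these lists passed. The largest ratio rises, at YIL001W and upstream of FRS2, were on probes not well above background on either before array. Their IP channel was at least 1.43-fold and 1.83-fold higher after, a bound that was not itself tested. The ratio changes had adjusted p = 5.0e-07 and 4.6e-05 in limma, although they turned to -0.10 and -0.11 with normexp. In all 658 probes changed, 353 higher and 305 lower. Centring on the mode gave 49 higher and 427 lower, and the count was 373 without control before replicate 1.

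The strains were compared directly as the degron change minus the control change. H4 over Pol III genes fell less in the degron strain. Here 50 of 77 probes differed, all towards the degron strain (52 and 2 the other way adjusted over the list alone), with a median difference of 0.76 (adjusted p = 8.8e-24; adjusted p = 0.16 with an estimated correlation). The array means over Pol III genes went from 0.22 ± 0.09 to -0.02 ± 0.15 in the degron strain and from 0.13 ± 0.10 to -0.76 ± 0.04 in the control strain (SD, n = 2). The difference was 0.65 (SE 0.06 with same-numbered arrays taken as pairs, two-sided exact permutation p = 0.333, the smallest that 2 pairs against 2 allow). Without pairing, over probes well above background, it was 0.64 with an SE of 0.15. SUF11 differed by 1.70 (SE 0.15), the interval between COQ6 and YNCG0046W by 1.55 (SE 0.12, adjusted p = 1.4e-06) and GAL1 by 0.90. The difference ran the other way at HHT1 (-1.86, SE 0.21), between ECM15 and NTH2 (-1.39, SE 0.13) and at ERG26 of sterol synthesis (-1.21). These turned positive with normexp, and HHT1 and ERG26 after loess too (0.16 and 0.27).

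In all 349 probes differed between the strains, 188 higher and 161 lower. No other list passed. Histone genes had 2 higher and 8 lower of 36 (10 adjusted over the list alone; median -0.07, turning to 0.10, 0.09 and 0.17 with normexp, loess and the mode) and ribosomal protein genes 3 lower of 19 (2 adjusted over the list alone; -0.20, turning to 0.06 with the mode). With one spread ribosomal protein genes passed (-0.30, adjusted p = 0.046). Galactose genes had 2 higher of 7 and passed in the authors' values (0.25, adjusted p = 0.0049), with outlier spots kept (0.25, adjusted p = 0.0046) and with one spread (0.18, adjusted p = 0.046). The snoRNA genes had 1 higher and 2 lower of 28. The count was 230 with the replicate number as a block, 207 centred on the mode (196 higher and 11 lower) and 177 without control before replicate 1. Each strain lies on a slide of its own, so slide and strain cannot be told apart.

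Rpc82 ChIP measured Pol III on its genes. Before induction Pol III gene probes averaged 4.41 ± 0.03 log2 in the degron strain and 3.82 ± 0.18 in the control strain (SD, n = 3). After induction the degron mean was 3.31 ± 0.65 and the control mean 3.75 ± 0.30 (exact permutation p = 0.1, the smallest possible with 3 against 3, and 0.9, two-sided). In limma Pol III genes fell in the degron strain, 16 of 83 probes lower and none higher (46 lower adjusted over the list alone; median -0.94, adjusted p = 2.3e-28; adjusted p = 0.18 with an estimated correlation). Lower probes numbered 32 with normexp (11 higher), 40 after loess (4 higher), 37 with the replicate number as a block, 32 with outlier spots kept, 6 without saturated spots and 2 with one spread.

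Of the 29 falls, 16 lie at probes saturated on every after array, at RDN5-1 and at tRNA genes such as YNCF0014C, YNCG0031W, YNCN0006W and SUP51, so no fold is given for them. Among the 43 Pol III probes never saturated, 40 lay below 0 in the degron strain and 5 fell. Array means over all 46 never-saturated Pol III probes, tested or not, went from 4.34 ± 0.07 to 3.70 ± 0.35 in the degron strain. This was a change of -0.64 (SE 0.21), against -0.15 (SE 0.21) in the control strain. The changes were 0.18 (SE 0.12) and 0.05 with normexp, and -1.15 (SE 0.13) and -0.94 (SE 0.20) after loess. The degron change was -0.59 centred on the mode and in the authors' values, and -0.47 with one spread (SE 0.56). Named after their values were seen, unsaturated probes fell in RNA170 by 1.77 (SE 0.32, adjusted p = 0.028) and in SCR1 by 1.71 (SE 0.27, adjusted p = 0.019, 1 after array). The U6 RNA gene SNR6 was at -1.19 (adjusted p = 0.073) and RPR1 at -0.71 (adjusted p = 0.12).

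Outside the Pol III transcripts themselves Rpc82 rose in the degron strain by 1.37 near ZWF1 (SE 0.22, adjusted p = 0.010; from 0.56 ± 0.46 to 1.93 ± 0.15, n = 3), by 1.35 upstream of YOP1 beside YNCP0011C (SE 0.21) and by 1.20 upstream of DIF1 (SE 0.22; -1.07 after loess). It rose by 1.18 upstream of GPH1, glycogen phosphorylase (SE 0.25), by 1.16 near the tRNA gene IMT2 (SE 0.14, adjusted p = 0.0017) and by 1.00 near CDC42 (SE 0.19). CIT1, citrate synthase and the only carbohydrate gene, had 1 of 3 probes higher (3 adjusted over the list alone; median 0.72). PHO8 had none of 3 called over all probes and 3 lower adjusted over the list alone (-0.51). Ribosomal protein (0.20), histone (0.10), galactose (0.31), nitrogen (0.15), YPS1 (-0.05) and snoRNA lists (-0.01, with SNR17A at 0.58 rising and SNR85 at -0.91 falling) did not pass. Galactose genes passed in the authors' values (0.32, adjusted p = 0.028) and with outlier spots kept (0.30, adjusted p = 0.0092). In all 54 of 1724 probes changed, 25 higher and 29 lower. The count was 203 with normexp (118 higher and 85 lower), 175 after loess, and 159 in the authors' values (100 higher and 59 lower). It was 152 with the replicate number as a block, 122 with outlier spots kept, 7 with one spread and 10 without degron before replicate 1. The Pol III median was -0.50 without degron after replicate 2.

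In the control strain 7 probes changed for Rpc82, 2 higher and 5 lower. Rpc82 rose by 1.39 near PHO11 (SE 0.21, adjusted p = 0.015) and fell by 1.74 in the U5 RNA gene SNR7 (SE 0.23, adjusted p = 0.0060) and by 1.32 in RNA170 (SE 0.25). It fell by 1.07 near TFC3 (SE 0.19), by 3.71 upstream of FRS2 and by 3.26 near YIL001W. None of these directions held under every scaling. FRS2 turned to 0.31, YIL001W to 0.33, SNR7 to 1.05 and TFC3 to 0.60 with normexp, while RNA170 turned to 0.40 and PHO11 to -1.26 after loess. Pol III genes had 1 of 83 probes lower (2 adjusted over the list alone), with a median of -0.04 that turned to 0.70 with one spread. It also turned to 0.02 without control before replicate 1, to 0.05 without control before replicate 3 (list adjusted p = 0.31), to 0.04 without control after replicate 1 (list adjusted p = 0.47) and to 0.04 without control after replicate 2. The list stood below other probes (adjusted p = 0.0081; adjusted p = 0.77 with an estimated correlation), but above them with one spread (adjusted p = 0.00048). Called Pol III probes were 16 lower and 7 higher with normexp, 33 and 4 after loess, and 5 and 0 in the authors' values. YPS1 probes lay lower as a list with no single call (-0.34, adjusted p = 0.0031; adjusted p = 0.0040 with an estimated correlation). Galactose probes lay higher with no single call (0.32, adjusted p = 0.027; adjusted p = 0.28 with an estimated correlation), a call lost in the authors' values (adjusted p = 0.23) and after loess (adjusted p = 0.061). Ribosomal protein (0.15), histone (0.14), nitrogen (0.04) and snoRNA lists (0.11) did not pass, the first and last turning below 0 after loess. The count was 91 after loess, 84 in the authors' values, and 76 with normexp. It was 17 with a variance trend, 16 with the replicate number as a block, and 1 without control before replicate 2. The numbers pair these arrays.

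Between the strains, the change of Rpc82 over Pol III genes was lower in the degron strain at the median of 83 probes (-0.81, adjusted p = 5.2e-18 for the list; adjusted p = 0.28 with an estimated correlation; 1 probe lower adjusted over the list alone). The difference was -0.50 in array means over never-saturated probes (SE 0.25, exact permutation p = 0.1, two-sided and the smallest possible; 0.13 with normexp and -0.21 after loess). The medians were -0.08 with normexp (adjusted p = 0.26), -0.09 after loess (adjusted p = 0.075) and -0.47 without degron after replicate 2. No probe passed for the difference in limma, with 164 at an unadjusted p under 0.05. The count was 20 in the authors' values, 10 with the replicate number as a block, 6 with normexp and 22 without degron after replicate 3. Probes at RDN37-1, YNCD0017W and RDN5-1 were saturated on every degron after array, so no fold is given for them. YPS1 (0.33), ribosomal protein (0.07), histone (-0.04), galactose (0.01), nitrogen (0.08) and snoRNA genes (-0.01) did not pass, though YPS1 did with one spread (0.26, adjusted p = 0.039) and with outlier spots kept (0.38, adjusted p = 0.031).

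**Figure D2:**
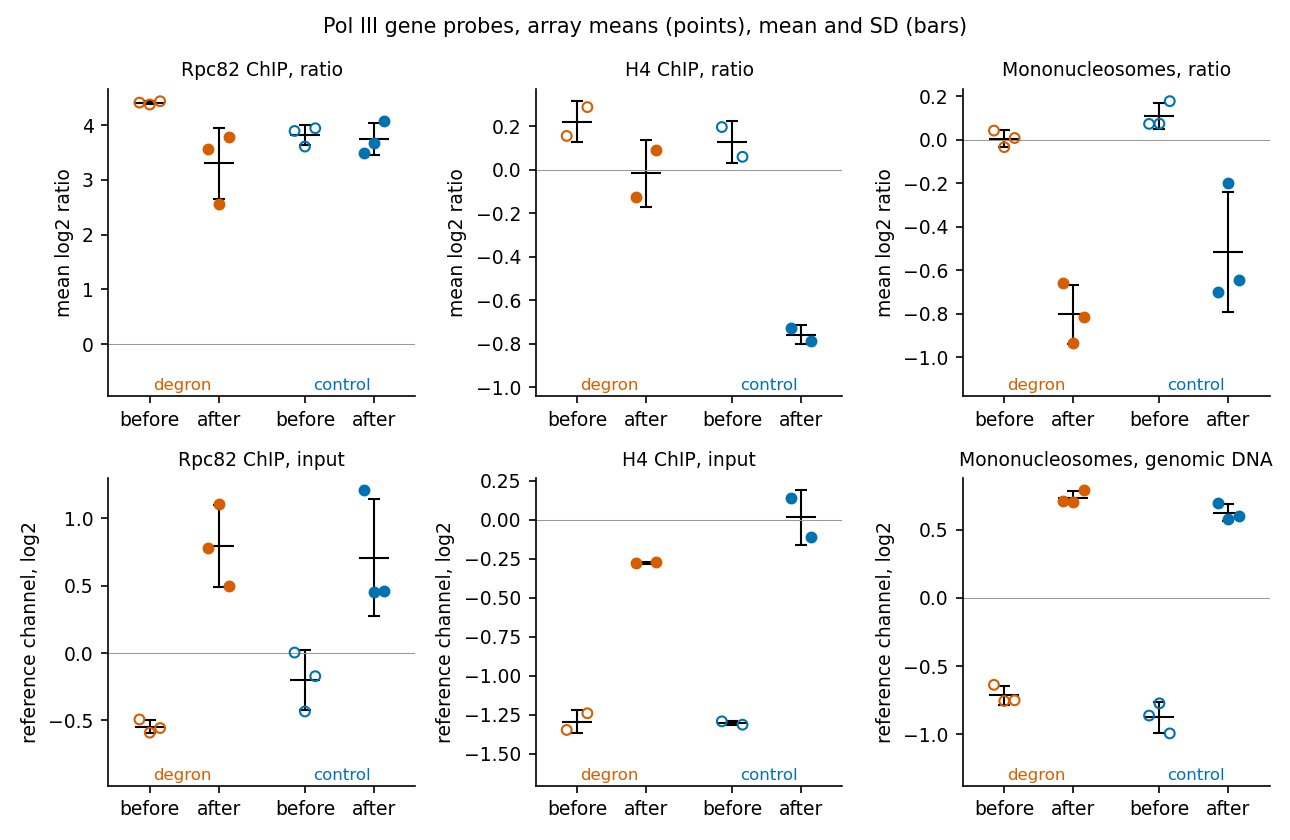
Mean over Pol III gene probes on each array (points; open before, filled after; degron strain in orange, control strain in blue) with the group mean and SD (bars), for Rpc82 ChIP, H4 ChIP and mononucleosomes. The upper panels give the log2 ratio and the lower panels the input or genomic DNA channel, in log2 relative to the median of the array. The H4 ratio of the control strain lies near -0.76 after induction, and in the lower panels every group lies higher after induction than before.

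The reference channel moved with induction in the same samples. Over Pol III genes the input or genomic DNA channel, relative to its array median, was higher after induction by 1.34 and 0.91 log2 in the Rpc82 arrays (degron and control strain) and by 1.02 and 1.32 in the H4 arrays. It was higher by 1.45 and 1.50 in the mononucleosome arrays, while it moved by -0.03 for Rsc3 and 0.02 for Rsc8. In rpb1-1, where the non-permissive samples came second on the arrays, it moved by -0.44 (SE 0.12). The IP or mononucleosome channel was also higher, by 0.29 and 0.86 for Rpc82, 0.76 and 0.43 for H4 and 0.61 and 0.87 for mononucleosomes. The ratios above hold the difference of these changes.

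Mononucleosome maps addressed where nucleosomes moved, appeared or were lost. In the degron strain signal rose by 1.57 upstream of COX19, a mitochondrial copper protein gene (SE 0.12, adjusted p = 4.7e-06; from -1.67 ± 0.15, n = 2, to -0.11 ± 0.12, n = 3) and by 1.35 between LSM3 and MRPL4 (SE 0.09). It rose by 1.31 upstream of RIO1, a kinase gene (SE 0.11, 1 after array), by 1.15 between LEU4 and MET4 of amino acid metabolism (SE 0.08, adjusted p = 5.7e-07) and by 1.14 upstream of GRH1 (SE 0.09). Over tRNA genes it fell by 3.32 in YNCB0018W (SE 0.17, adjusted p = 3.9e-08; from 3.79 ± 0.33 to 0.47 ± 0.21, n = 3). The changes were -3.15 in YNCM0010W, -2.65 in YNCP0018C and -2.46 in YNCG0046W. In YNCB0018W and YNCM0010W they turned to 0.40 and 0.30 with normexp and to 0.19 and 0.06 after loess. In all 702 of 1501 probes changed, 319 higher and 383 lower. The 33 runs of at least 3 neighbouring called probes, 11 higher and 22 lower, included 5 probes of LEU4/MET4 (chromosome XIV, 426893 to 427266, mean 0.83). Runs of 4 lay at RDN5-1 (-1.13, where 1 probe turned to 0.06 after loess), ERG26 (-1.08), IMT4 (-0.98), ECM15/NTH2 (-0.97) and MNN1 (-0.84).

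The control strain changed much alike. Signal rose by 1.68 upstream of ORM2 (SE 0.08, adjusted p = 7.5e-07), by 1.48 in the snoRNA gene SNR31 (SE 0.13), by 1.46 between LSM3 and MRPL4 (1 after array), by 1.42 upstream of COX19 (1 after array) and by 1.38 upstream of RIO1 (SE 0.08). It fell by 2.69 in YNCG0046W (SE 0.18), and the changes were -2.64 in YNCP0018C, -2.25 in YNCB0018W (0.64 with normexp and 0.93 after loess) and -1.69 in SNR6 (0.25 after loess). Here 824 probes changed, 389 higher and 435 lower, with 43 runs, 15 higher and 28 lower. FAT1, a fatty acid transporter gene, fell over the 6 of its 8 probes that were measured (chromosome II, 317674 to 318238, mean -0.72). At LEU4/MET4 8 of 9 probes rose, and NTH1, a trehalase locus, held a run of 4 at -1.07. The strains shared 541 called probes, 227 higher and 304 lower in both and 10 opposite, where independent lists would share 82.7 and 111. Their changes correlated across probes with r = 0.83.

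Pol III genes fell in the degron strain, 45 of 78 probes lower and 1 higher (1 higher and 49 lower adjusted over the list alone; median -0.59, adjusted p = 5.9e-11; adjusted p = 0.33 with an estimated correlation; -0.06, adjusted p = 0.57 after loess). They fell in the control strain too, 43 lower and 6 higher (6 and 44 adjusted over the list alone; -0.52, adjusted p = 9.5e-07; adjusted p = 0.68 with an estimated correlation), where the median turned to 0.03 after loess (adjusted p = 0.86) and was -0.12 with normexp (adjusted p = 0.46). Called Pol III probes were 32 lower and 7 higher with normexp and 20 and 12 after loess in the degron strain, and 22 and 12, then 22 and 22 in the control strain. Gene body probes rose more often than they fell, 148 higher and 58 lower of 378 in the control strain (median 0.16, adjusted p = 4.0e-05; adjusted p = 0.026 with an estimated correlation). In the degron strain 96 rose and 56 fell (0.09, adjusted p = 0.0040; adjusted p = 0.15 with an estimated correlation). The medians lay above 0 under every scaling tried.

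No other list passed in the mononucleosome maps. In the degron and the control strain, ribosomal protein genes had 3 higher and 8 lower of 22 probes in each (-0.21, turning to 0.03 with normexp, and -0.06, turning to 0.02 with normexp and with the mode). RPS20 among them fell by 1.39 in the degron strain. Histone genes had 8 higher and 3 lower, then 7 and 7 of 33 (0.10, turning to -0.14 with normexp and -0.02 with one spread, and 0.00), and galactose genes 2 and 4, then 2 and 5 of 9 (-0.24 and -0.57; GAL1 fell by 0.86 and by 1.31). In the control strain galactose genes passed with outlier spots kept (-0.60, adjusted p = 0.035). The snoRNA genes had 5 and 8, then 6 and 6 of 24, nitrogen genes 3 and 0, then 4 and 3 of 12, and YPS1 2 and 0, then 1 and 2 of 5. Adjusted over the list alone the calls were 11 and 11, 11 and 13, 6 and 7, 13 and 12, 3 and 7, and 2 and 3. With the replicate number as a block, which needs complete pairs, 443 and 488 probes passed. The degron count was 1159 in the authors' values and 1097 with outlier spots kept. Centring on the mode split the calls 336 higher and 243 lower in the degron strain and 368 and 272 in the control strain.

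The strains differed at 38 probes in the mononucleosome change, 12 higher and 26 lower for the degron strain. The degron strain gained relative to the control upstream of TFB4, a TFIIH gene, by 1.01 (SE 0.14, adjusted p = 0.0044) and upstream of the Mediator gene SRB4 by 0.91 (SE 0.14, 1 degron after array). Upstream of TIM23 the gain was 0.76 (SE 0.12; -0.90 ± 0.14 to -0.39 ± 0.03 in the degron strain and -0.70 ± 0.06 to -0.95 ± 0.11 in the control strain, n = 3), at COX19 0.75, upstream of YDL129W 0.74 and between LEU4 and MET4 0.60. It lost relative to the control upstream of the snoRNA gene SNR85 by 1.20 (-1.20, SE 0.15, adjusted p = 0.0023), near TOS3 (-1.11, 0.03 with normexp), in the tRNA genes YNCE0016C (-1.19), YNCP0009W (-1.10) and YNCB0018W (-1.07), and at RSC30/CPR2 (-0.97).

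Pol III genes had 5 of 78 probes lower and none higher (7 lower adjusted over the list alone; median -0.08, adjusted p = 0.055), where the median turned to 0.04 in the authors' values and to 0.11 without control after replicate 2. Lower probes numbered 11 in the authors' values (2 higher), 8 with one spread, 2 after loess and 3 centred on the mode. At the preset correlation the list passed with the replicate number as a block (-0.09, adjusted p = 0.0026), centred on the mode (-0.08, adjusted p = 0.0093), with one spread (-0.18, adjusted p = 0.0013) and with outlier spots kept (-0.11, adjusted p = 0.032). It also passed without degron before replicate 2 (-0.12), degron after replicate 1 (-0.15), control before replicate 3 (-0.12) and control after replicate 1 (-0.22) or 3 (-0.18). With an estimated correlation and the main values, the 77 Pol III probes never saturated gave p = 0.50 in limma's camera. Ribosomal protein genes had 1 of 22 lower, at RPL26A (-0.73, 1 control after array; 1 adjusted over the list alone; list median -0.14, turning to 0.08 with normexp). Histone (0.10), galactose (0.22), nitrogen (0.07, turning to -0.12 with normexp), YPS1 (0.22) and snoRNA genes (-0.04) did not pass. Galactose genes passed with one spread (0.29, adjusted p = 0.0057) and with normexp (0.43, adjusted p = 0.039), and histone genes with outlier spots kept (0.12, adjusted p = 0.032). The count was 21 with the replicate number as a block, 19 centred on the mode, 82 with one spread (39 higher and 43 lower), 95 with outlier spots kept, and 139 with normexp (76 and 63). It was 223 in the authors' values (119 and 104), 14 without degron after replicate 2 and 93 without control before replicate 1, and loess split the calls 29 higher and 15 lower.

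**Figure D3:**
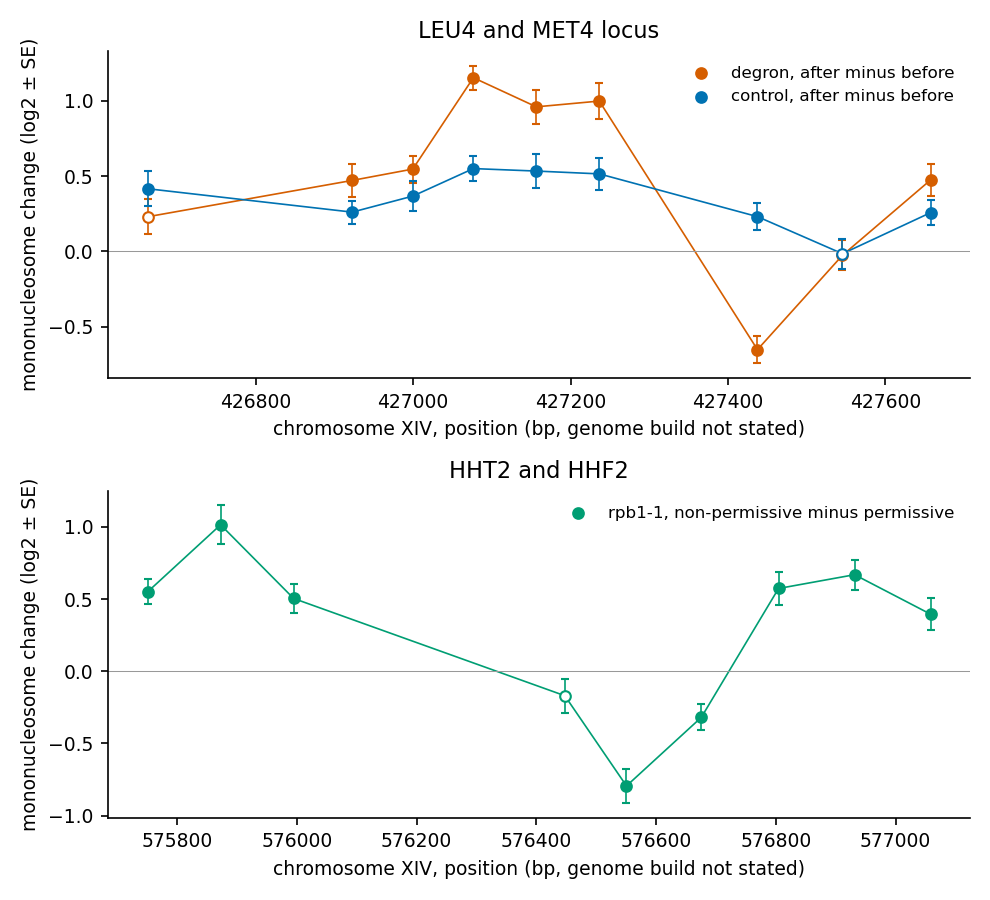
Mononucleosome change (log2, with SE) along the LEU4/MET4 locus in the degron and control strains (upper panel) and along HHT2/HHF2 in rpb1-1 cells (lower panel), against the position on chromosome XIV as the array design gives it. Filled points passed the test and open points did not. A run of 5 probes rose at LEU4/MET4 in both strains (means 0.83 and 0.44), and runs of 3 rose on each side of the HHT2/HHF2 interval (means 0.69 and 0.55).

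The rpb1-1 maps addressed nucleosome positions when Pol II is inactivated by heat. No strain with heat-stable Pol II was mapped under the same shift, so effects of heat and of Pol II inactivation cannot be told apart. Signal rose within genes, by 1.03 in SRP72 (SE 0.11, adjusted p = 0.0013) and by 1.02 at YCK2, a casein kinase gene (SE 0.08, adjusted p = 0.00017; from -0.88 ± 0.04 to 0.14 ± 0.08, n = 3). It rose by 1.01 in HHT2, a histone H3 gene (SE 0.13), by 0.98 in POL3, a DNA polymerase gene (SE 0.08, adjusted p = 0.00017), by 0.87 in SES1 (SE 0.08) and by 1.21 at SNR7 (SE 0.13, 1 permissive array). It fell by 1.05 in NCP1 (SE 0.16, 1 non-permissive array), by 1.00 upstream of DLD1, a lactate dehydrogenase gene (SE 0.12), by 0.90 near GAT1 (SE 0.09), by 0.87 upstream of RPR1 (SE 0.18) and by 0.80 in YCR022C (SE 0.14). Of 1183 probes 361 changed, 197 higher and 164 lower.

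Gene body probes rose in 88 and fell in 27 of 285 cases (median 0.11, adjusted p = 0.00056; adjusted p = 0.095 with an estimated correlation). Intergenic probes rose in 52 and fell in 108 of 565 (-0.06, adjusted p = 0.00022; adjusted p = 0.072 with an estimated correlation). These directions were the same under every scaling tried, with 43 and 7 gene body and 14 and 36 intergenic probes called centred on the mode. Called runs of at least 3 probes numbered 11, 4 higher and 7 lower. Rises lay at SNR7 (0.87), POL3 (0.82) and HHT2/HHF2 and falls at DIF1/CAR2 (chromosome XII, 1012161 to 1012546, -0.70), FTR1, an iron permease gene (-0.57), and AGX1 (-0.51). At HHT2/HHF2 6 of 9 probes rose, and at STP4 4 of 6 fell.

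No list passed in rpb1-1. Histone genes had 11 higher and 5 lower of 26 probes (16 adjusted over the list alone; median 0.09) and galactose genes 4 higher of 7 (4; 0.31), among them GAL1 at 0.66. Ribosomal protein genes had 5 higher and 1 lower of 15 (6; 0.19), among them RPS3 at 0.60, and nitrogen genes 1 and 3 of 9 (4; -0.17). PHO8 had 1 higher of 5 (2; -0.25), snoRNA genes 1 and 1 of 17 (2; 0.05) and Pol III genes 9 and 5 of 66 (13; 0.13, turning to -0.06 with normexp, -0.02 in the authors' values, with 12 higher and 19 lower, and 0.00 after loess). YPS1 had no call (-0.20), and HHF2 had 2 higher and 2 lower of 5 probes. Replicates 1 and 2 lie on 1 slide and replicate 3 on another. With the slide as a block 269 probes passed, on the first slide alone 5 passed, and the other holds 1 array per group. The count was 859 in the authors' values, 776 with outlier spots kept, 123 centred on the mode and 141 without permissive replicate 3.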

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

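The tests of saturation, input brightness, probe GC content, slide and session, intensity bias and loss of Sth1 in this part were chosen only after the results were seen. A difference between the degron and the control strain in limma's interaction test put the results here: 349 probes and the Pol III genes (median difference 0.76 log2) for H4, the Pol III genes (-0.81) for Rpc82, and 38 probes for mononucleosomes.

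Rpc82 over Pol III genes was lower after induction in the degron strain than the control strain's change would give, by -0.81 log2 at the median (list adjusted p = 5.2e-18; adjusted p = 0.28 with an estimated correlation). Saturation of the immunoprecipitated channel stays open: at the 40 probes saturated at least once (-1.53) a capped signal lowers the ratio by an unknown amount, and the array means of never-saturated probes changed by -0.64 in the degron strain (SE 0.21) but by 0.18 with normexp (SE 0.12). An intensity-dependent bias between the channels has the value it needs, with a median difference of -0.091 after loess (adjusted p = 0.075; -0.080 with normexp, adjusted p = 0.26), where the control strain's median was -0.56 and the degron strain's -0.92. Pol III probes lie far above the array median in this IP channel (3.71 log2 before induction in the degron strain). Loess would therefore also remove a real change there, so the test cannot decide. A brighter input channel also stays open, since over never-saturated probes it moved by 0.24 more in the degron strain (SE 0.18, exact permutation p = 0.2). Loss of Sth1 stays open as well, at -0.50 in the ratio of the same probes (SE 0.25, exact permutation p = 0.1, the smallest 3 arrays against 3 allow), and dye and strain coincide here.

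The H4 ratio over Pol III genes fell at the median by 0.97 in the control strain and by 0.21 in the degron strain (adjusted p = 0.018 and 0.46 with an estimated correlation). Both channels rose there in array means. The input moved by 1.32 in the control strain and 1.02 in the degron strain, and the IP by 0.43 and 0.76. Probe GC content is argued against, because the control median was -1.0 with the GC trend of the other probes removed. Slide and scan session stay open: each strain lies on a slide of its own, and the input channel over Pol III genes moved by -0.30 in the degron strain relative to the control strain (SE 0.12, exact permutation p = 0.333). Loss of Sth1 stays open too, with a difference of 0.65 in array means (SE 0.06 with same-numbered arrays taken as pairs, exact permutation p = 0.333, the smallest that 2 pairs against 2 allow).

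Mononucleosome signal over Pol III genes fell in both strains, with medians of -0.59 in the degron strain and -0.52 in the control strain (adjusted p = 0.33 and 0.68 with an estimated correlation). Probe GC content is argued against, because the degron median was -0.73 with the GC trend removed. An intensity-dependent bias between the channels has the value it needs, with a median of -0.063 after loess (adjusted p = 0.57 in limma's camera), although loess would also remove a real change that goes with intensity. A brighter genomic DNA channel stays open: it moved by 1.45 over Pol III genes in the degron strain (SE 0.05), and array use and induction coincide, but the same order of use came with -0.03 for Rsc3 and 0.02 for Rsc8. The design gives no biological explanation for a change shared by the strains other than galactose and heat, which was not tested apart.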

How the results depend on the processing

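Keeping non-uniform spots, leaving out saturated spots and using 1 rpb1-1 slide alone were chosen after the data had been seen. Signal over background was at least 35.5 in green and 14.9 in red. Restricting the tests to probes well above background moved no count past 1.5 times, but the Pol III list lost its call in the Rsc3 and Rsc8 enrichment (adjusted p = 0.052 and 0.059). Of 7097 values of named probes under other settings, 6285 kept their direction and side of the threshold, 752 kept their direction only, and 60 turned, of which 38 with normexp, 18 after loess, 3 in the authors' values and 1 with non-uniform spots kept. The cause was not tested for any of the changes below, except where fewer arrays were tested. With normexp the background correction changes and the scanner's dye normalization is absent, so their effects cannot be told apart. Feature means and other feature widths were not run because the build is not given, and the slide could be a block only for rpb1-1 (269 calls).

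Without a size minimum, 737 of 1467 probes with adjusted p under the threshold lay above the array median for Rsc3, and 695 of 1356 for Rsc8. The others lay below it, because arrays are centred on the median, so these are not counts of bound probes. In the counts below, bound stands for a call with the 1 log2 minimum. With normexp the counts were 22 (Rsc3 bound), 5 (Rsc8 bound), 203 (Rpc82 degron), 76 (Rpc82 control), 6 (Rpc82 strain difference) and 139 (mononucleosome strain difference). The Pol III medians were -0.090 (H4 degron), -0.080 (Rpc82 strain difference) and -0.12 (mononucleosome control). After loess the counts were 1 (Rsc3 bound), 175 (Rpc82 degron) and 91 (Rpc82 control), with Pol III medians of -0.091 (Rpc82 strain difference), -0.063 (mononucleosome degron) and 0.026 (mononucleosome control). Centred on the mode, counts were 2 (Rsc8 bound), 683 (Rsc3 change), 304 (Rsc8 change), 16 (Rsc8 minus Rsc3), 114 (H4 degron), 207 (H4 strain difference), 19 (mononucleosome strain difference, Pol III median -0.077) and 123 (rpb1-1). The mode moved the median of all probes by -0.19 in control H4, 0.19 in the H4 strain difference, 0.11 in control Rpc82 and 0.10 in control mononucleosomes. One spread moved it by 0.13 in control Rpc82. With one spread, counts were 0 (Rsc3 bound), 661 (Rsc3 change), 0 (Rsc8 minus Rsc3), 7 (Rpc82 degron), 3 (Rpc82 control, Pol III median 0.70) and 82 (mononucleosome strain difference, Pol III median -0.18). In the authors' values, counts were 5 (Rsc3 bound), 159 (Rpc82 degron), 84 (Rpc82 control), 20 (Rpc82 strain difference), 1159 (mononucleosome degron), 223 (mononucleosome strain difference, Pol III median 0.036) and 859 (rpb1-1).

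With the replicate number as a block, counts were 281 (H4 degron), 230 (H4 strain difference), 152 (Rpc82 degron), 16 (Rpc82 control), 10 (Rpc82 strain difference), 443 and 488 (mononucleosome degron and control) and 21 (mononucleosome strain difference, Pol III median -0.085). The block moved no other count past 1.5 times, and of 298 values of named probes 272 stayed on their side of the threshold and 26 lost their call with the direction kept. Among strains with 3 pairs only in control Rpc82 did every array correlate best with its own number. A variance trend gave 17 (Rpc82 control) and leaving out saturated spots 12 (Rpc82 control). With non-uniform spots kept, counts were 122 (Rpc82 degron), 16 (Rpc82 control), 1097 (mononucleosome degron), 95 (mononucleosome strain difference, Pol III median -0.11) and 776 (rpb1-1). With the control sign turned, the Pol III median was 0.037 (Rpc82 control) by construction and the Rpc82 strain difference had 103 calls, while the correlation with the degron arrays decides the sign (r -0.975 to -0.832 before turning). Slide 4 alone gave 5 calls in rpb1-1. With an estimated correlation the Pol III lists lost their calls at unchanged medians: H4 degron -0.21, H4 strain difference 0.76, Rpc82 degron -0.94, Rpc82 control -0.037, Rpc82 strain difference -0.81, mononucleosome degron -0.59 and control -0.52. Over all comparisons 34 lists passed with the preset and 5 with the estimated correlation.

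Leaving out 1 array at a time, where a group left with 1 array is assumed to vary like the others, gave these ranges. Counts were 5 to 9 (Rsc3 bound), 0 to 1 (Rsc8 bound), 864 to 1111 (Rsc3 change), 432 to 787 (Rsc8 change), 18 to 264 (Rsc8 minus Rsc3), 236 to 469 (H4 degron), 373 to 612 (H4 control), 177 to 379 (H4 strain difference), 10 to 78 (Rpc82 degron), 1 to 13 (Rpc82 control), 0 to 22 (Rpc82 strain difference), 573 to 737 (mononucleosome degron), 637 to 801 (mononucleosome control), 14 to 93 (mononucleosome strain difference) and 141 to 411 (rpb1-1). Pol III medians ranged from -0.19 to 0.048 (Rpc82 control) and from -0.22 to 0.11 (mononucleosome strain difference).

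Named probes that turned with normexp were, for Rsc8 minus Rsc3, MIL1/RIM15 (0.10) and SCR1 (0.11). For H4 degron they were HHF1/HHT1 (0.14), SCR1 (0.26) and YNCP0009W (0.29). For H4 control they were YIL001W (-0.10), FRS2/GAT1 (-0.11), HHF1/HHT1 (-0.11), YNCD0007C (the probe upstream of SES1, -0.032) and ERG26 (-0.093). For the H4 strain difference they were YIL001W (0.23), HHF1/HHT1 (0.25), FRS2/GAT1 (0.24), ECM15/NTH2 (0.21), ERG26 (0.22), IRC22/MNN1 (0.19), PHO11 (0.29), DNM1/YLR001C (0.21) and SNR31/SNR5/HEM4 (0.12). For Rpc82 control they were FRS2/GAT1 (0.31), YIL001W (0.33), TOS2/SNR7/PET54 (1.05) and TFC3 (0.60). For mononucleosomes they were, in the degron strain, YNCB0018W (0.40), YNCM0010W (0.30), YNCE0018W (0.031), YNCE0016C (0.61), TRT2 (0.32), YNCP0009W (0.49) and NUP188/SNR85/CAC2 (0.33), and in the control strain YNCE0018W (0.48), YNCM0010W (0.60), YNCB0018W (0.64) and SNR69/RGT1 (0.35). Between the strains they were TOS3 (0.027), AGE1/RBA50 (0.12) and TRR4 (0.087), and in rpb1-1 TFC3 (-0.0046).

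After loess they were, for the H4 strain difference, HHF1/HHT1 (0.16), FRS2/GAT1 (0.11), ERG26 (0.27) and PHO11 (0.28), for Rpc82 degron DIF1/CAR2 (-1.07), and for Rpc82 control PHO11 (-1.26) and RNA170 (0.40). For mononucleosomes they were, in the degron strain, YNCB0018W (0.19), YNCM0010W (0.061), YNCE0018W (0.071), YNCE0016C (0.41), TRT2 (0.10), YNCP0009W (0.33) and RDN5-1 (0.060), and in the control strain YNCE0018W (0.36), YNCM0010W (0.56), YNCB0018W (0.93) and SNR6 (0.25). In the authors' values YNCO0008W turned in control mononucleosomes (-0.12) and between the strains (0.62), as did RPR1 (0.15), and with non-uniform spots kept YNCO0008W (0.060) between the strains.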

Other observations

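Every neighbour count, place, correlation and regrouping in this part was chosen only after the results were seen, and correlations are across probes, which are not independent replicates. Next to Pol III genes, H4 moved with the genes in the control strain: of 277 neighbouring probes in the same loci 100 fell and 38 rose (median -0.11), while at 1160 probes of other loci 135 fell and 314 rose (0.08). Centred on the mode the medians were -0.35 (126 fell and 4 rose) and -0.15 (229 and 45), so the falls beside the genes kept their direction and the other loci turned. The strain difference at the neighbours was 0.14, with 76 probes higher and 14 lower in the degron strain, against -0.09 elsewhere with 62 higher and 147 lower, a side that turned to 0.15 with 72 higher and 11 lower centred on the mode (neighbours 0.37, 75 and 0). Beside Pol III genes Rsc3 also moved with them, 170 of 348 neighbouring probes rising and 17 falling (0.10; 101 and 8 with one spread), and Rsc8 rose at 111 and fell at 19 (0.07; 25 and 5 centred on the mode). Gene body probes had lower H4 in the degron strain than the control strain's change would give, 3 higher and 38 lower (-0.15, adjusted p = 5.4e-06; adjusted p = 0.28 with an estimated correlation), which turned to 0.10 with 2 higher and 2 lower centred on the mode, against 0.25 at other probes. RNA170, a Pol III gene, went against its class for mononucleosomes, rising by 1.04 in the degron strain (SE 0.10).

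Rsc3 and mononucleosome changes were opposite in sign at many probes. The Rsc3 change after mock induction correlated with the mononucleosome change at r = -0.39 in the degron strain and -0.33 in the control strain (-0.31 and -0.23 without the GC trend, 1500 probes). Of 396 probes called in the Rsc3 and degron mononucleosome comparisons 292 went opposite ways. The Rsc3 level before induction correlated with the mononucleosome change at r = 0.33 in the degron strain and 0.31 in the control strain. Before induction the Rsc3 and mononucleosome levels already correlated at r = -0.29 and -0.28. Array SDs went from 0.27 to 0.31 down to 0.18 to 0.24 for Rsc3. In degron mononucleosomes they went from 0.74 to 0.76 down to 0.53 to 0.64. Narrowing towards the array median in each assay would give correlations of these signs, so they show no link between the responses. The H4 changes of the degron and control strains correlated at r = 0.40, and of 245 probes called in both 106 were higher, 109 lower and 30 opposite, where independent lists would share 48.7 and 49.4. The rpb1-1 and control mononucleosome changes correlated at r = -0.24, with 139 of 195 shared calls opposite. The order of array use is also opposite there, and the genomic DNA channel over Pol III genes moved by -0.44 and 1.50, so array use and treatment cannot be told apart.

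One hypothesis was that loss of Sth1 changes nucleosomes more where more Rsc3 lies. The signed strain difference in mononucleosome change, where gains and losses cancel, leaves this open (r = 0.043 with the Rsc3 level before induction). The size of that difference without its sign correlated with the Rsc3 level at r = -0.016 (SE 0.034 from resampled loci, rank correlation 0.03), which argues against an r above 0.1 across these probes. Measurement noise lowers such correlations.

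Arrays were regrouped in the 10 ways that keep 3 against 3. For Rsc3 1 of 10 groupings, the real one, called as many probes as the real one (1069, and at most 0 in another). The same 1 of 10 held for Rsc8 (709 against 0), Rsc8 minus Rsc3 (172 against 0), Rpc82 in the degron strain (54 against 3) and in the control strain (7 against 2), and mononucleosomes in the degron strain (702 against 1), in the control strain (824 against 10), between the strains (38 against 1) and in rpb1-1 (361 against 0). For the Rpc82 strain difference, with 0 calls, all 10 groupings called as many and the highest called 1. The numbers pair the control Rpc82 arrays, and of the 4 groupings that part all 3 pairs the real one called 7 (16 with the number as a block) and the others 0 with either fit, while the 6 that keep 2 pairs whole called at most 2. With 10 groupings the share cannot fall under 0.1, and H4 with 2 arrays per group was not regrouped. Every other grouping mixes arrays of both real groups, which widens the spread within groups and by itself lowers its calls. In comparisons of after with before and in rpb1-1, the real grouping also parts first from second use of the arrays. The counts therefore cannot tell induction from array use.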
